A study of Homo sapiens with 53 samples.

How the data were processed

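RNA from 53 libraries of NGN2-induced neurons was measured by poly(A) sequencing on a NovaSeq: 5 lines (the parental PGP-1 line and 4 edited clones) at 3 days, which make 15 groups. The values used are raw counts per Ensembl gene as deposited by the authors. Per the submitters' processing notes they were made with STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2 on GRCh38; the annotation and the settings for strand and for reads with several positions are not given in the sources used here. The table holds 17377 genes and its smallest value is 5, reached in 49 libraries, so genes with a lower count in any library had been removed before deposit, and genes silent in any line are not analysed here. A symbol was found for 17229 of the identifiers and not for 148. GENCODE release 29 holds 17314 of them, and 14029 are protein coding. Genes that have only an identifier were tested but left out of the named genes, as were some genes of the sex chromosomes.

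Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest). filterByExpr removed no gene, so a fit with no filter was the same fit. Each day was fitted on its own with the 3 genotypes as groups, which gives the 9 comparisons between genotypes. The 2 clones of a genotype were pooled, so that the spread within a genotype holds the difference between its clones. Libraries of a clone were still taken as independent, so p-values can be too small where such libraries correlate. That correlation within lines was 0.22, 0.55 and 0.03 in limma-voom at days 28, 42 and 56. A second fit with the 5 lines as groups set each clone against the parental line. A fit of all libraries with 9 groups of genotype and day gave the comparisons over time and the interactions between genotype and day. The p-values were adjusted by the method of Benjamini and Hochberg within each comparison, with a threshold of 0.05. In sentences that give no other test, adjusted p-values of single genes come from edgeR and those of gene lists from camera in limma 3.58.1. Levels are given in CPM, scaled by TMM. The 4 edited clones were also split 2 against 2 in each of the 3 possible ways on the edited libraries alone. XPO7 levels and mitochondrial shares were compared by exact two-sided permutation tests in R, which shuffle single libraries and not whole clones. Python 3.11.15 was used for tables and figures (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9). The mitochondrial share counts 30 genes of the mitochondrial genome.

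Gene lists, 58 in number, were fixed before the data were examined, as were the comparisons, the tests, the threshold, the rule for named genes and the alternatives not said below to be later. Of these lists 57 had at least 5 members in the table and were tested by camera on voom values with a preset correlation between genes of 0.01. The test was run again with the correlation estimated from the data. Genes named against the parental line are XPO7, the 6 highest and the 6 lowest log2 fold changes, up to 4 members of lists, and sodium channel genes whatever they showed. Some genes chosen by these rules are not reported here. The highest and lowest were taken among protein-coding genes with a mean of at least 2 CPM that passed the threshold in the pooled fit and in each clone alone with the same sign. List members were taken by smallest adjusted p from lists that passed camera or had at least 3 members past the threshold. For the other comparisons the 5 highest and 5 lowest genes past the threshold with a mean of at least 2 CPM were used.

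The comparisons were tested on simulated data with the group sizes, depths and spread of these libraries, in which 200 genes of the libraries labelled homozygous were changed, 50 for each of 4 sizes. Of genes changed 2-fold, 82%, 86% and 86% were recovered against the parental line at days 28, 42 and 56. For genes changed 1.5-fold the rates were 48%, 56% and 40%, for 1.25-fold 10%, 30% and 8%, and for 4-fold 98% at each day. For 2-fold changes they were 88%, 86% and 82% between the labelled genotypes, 70% in the interaction and 88% between parental days 28 and 42. In the comparison with no simulated change no gene was called at any day. Simulated clones did not differ and few genes changed, so these rates cover neither clone differences nor comparisons in which most genes pass. Library totals ran from 20.4 to 70.2 M counts with a median of 45.9 M.

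Alternatives planned were RLE scaling, DESeq2 1.42.0, another filter (at least 1 CPM in at least 6 libraries), replicate number as a block, the line as a random block in limma-voom, the 5 lines as groups, all 3 days in one fit, only the 2 genotypes compared, glmTreat against a fold of 1.5, the fry rotation test, leaving out each library in turn, and leaving out each clone in turn for counts of genes. Leaving out each clone for single genes and gene lists, and each library for gene lists and genes in both clones, was added after seeing the data. So were upper-quartile scaling, libraries thinned to 20.4 M counts each, removal of each library's trend on GC content and length (known for 17308 genes, 99.6%), fits without mitochondrially encoded genes or without the 2 shallowest libraries, fits of the parental libraries alone, and fits with replicates 1 and 3 or with replicate 2 of the edited clones alone. Replicate 4 of the parental line at day 28 is not among the samples given.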

Results

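Polyadenylated RNA was sequenced from excitatory neurons that had been made from the human induced pluripotent stem cell line PGP-1 by forced expression of NGN2, a proneural transcription factor. The series concerns XPO7, a gene linked to schizophrenia risk whose product carries cargo between nucleus and cytoplasm, together with neuronal excitability and sodium channels. The 53 libraries come from the parental line, 2 clones labelled heterozygous for an edit of XPO7 (A2 and D5) and 2 clones labelled homozygous (B1 and E12). Each clone was sampled at days 28, 42 and 56 with 3 libraries per day, and the parental line with 5 libraries at day 28 and 6 at each later day. Library totals ran from 20.4 to 70.2 M counts (M, mega-), with a median of 45.9 M. Totals at day 28 were 40.3 to 54.1 M in the parental line, 43.9 to 63.9 M in clones labelled heterozygous and 46.6 to 70.2 M in clones labelled homozygous. The ranges were 44.3 to 54.8, 27.9 to 40.4 and 32.2 to 39.7 M at day 42, and 50.3 to 54.1, 20.4 to 40.8 and 22.6 to 51.3 M at day 56. At these depths the biological coefficient of variation between libraries of a genotype was 0.173 at day 28, 0.172 at day 42 and 0.218 at day 56. The labels name a single batch and do not say that the replicates are separate cultures, so the p-values below measure the spread between these libraries, which may be technical.

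The first question is whether the edit shows in XPO7 itself (ENSG00000130227; GRCh38 chromosome 8, 21919671 to 22006585, plus strand). XPO7 was read in every library, and no group fell to a level near 0. At day 28 its level was 77.4 ± 2.4 CPM (counts scaled by edgeR to a common library total; SD, n = 5) in the parental line, 79.7 ± 13.3 (n = 6) in libraries labelled heterozygous and 95.1 ± 1.6 (n = 6) in libraries labelled homozygous. At day 42 the levels were 81.9 ± 2.6, 72 ± 3.6 and 85.2 ± 3.1 CPM, and at day 56 they were 94.1 ± 9.4, 67.1 ± 5.7 and 91.2 ± 7.9 CPM (n = 6 each). Against the parental line, XPO7 fell in libraries labelled heterozygous at day 42 (log2 fold change -0.20 ± 0.04, SE; exact permutation p = 0.00216, the smallest that these groups allow). It fell at day 56 as well (-0.53 ± 0.08, 0.69-fold with a 95% interval of 0.62 to 0.78; exact permutation p = 0.00216). No change passed the test at day 28 (0.03 ± 0.10, adjusted p = 0.792), but without A2 replicate 2 a rise of 0.13 did. In libraries labelled homozygous XPO7 rose at day 28 (0.30 ± 0.10, adjusted p = 0.0196; exact permutation p = 0.00216), a call of the model that ended without B1 (0.30), without E12 (0.29) and on replicate 2 of the clones alone (0.28). The values at day 42 (0.05 ± 0.04, adjusted p = 0.264) and day 56 (-0.09 ± 0.08, adjusted p = 0.374) did not pass. Libraries labelled homozygous had more XPO7 than those labelled heterozygous at day 42 (0.25 ± 0.04) and day 56 (0.44 ± 0.08; exact permutation p = 0.00216 each). At day 28 that difference was 0.26 ± 0.10 with an adjusted p of 0.102 in the model, against an exact permutation p of 0.00216 (0.16 and past the threshold without A2 replicate 2). All permutation tests were two-sided, and the 9 comparisons of XPO7 form one family. These tests shuffle single libraries, and 2 clones per label are too few for such a test on whole clones. The transcript levels thus go against the order that the labels give, and a count over the whole gene does not read the edited sequence. Libraries are therefore named by their labels, and every direction below is one between labels, not between measured losses of XPO7.

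**Figure D1:**
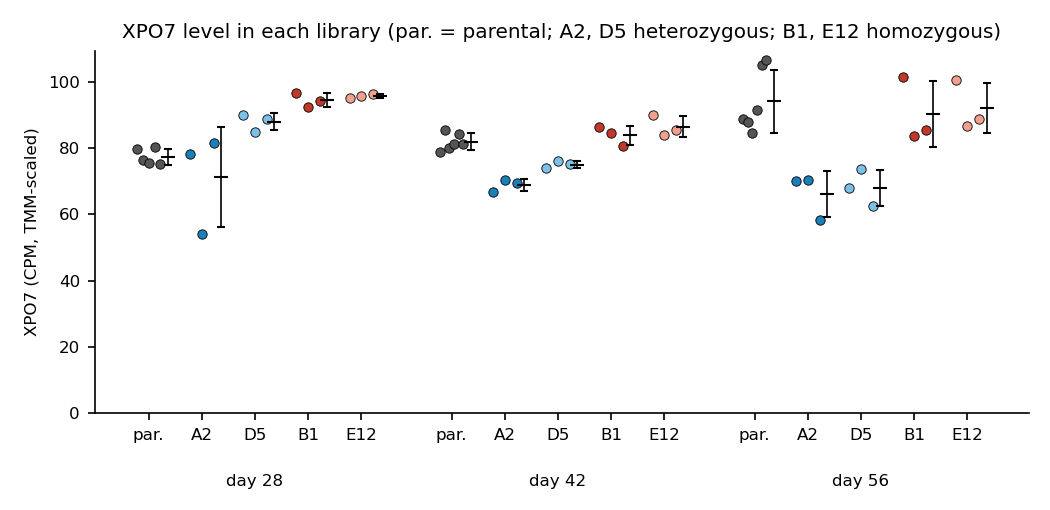
XPO7 in CPM (TMM-scaled, linear axis from 0) in each of the 53 libraries by line and day; bars give the mean and SD of each line, and par. stands for the parental line. All libraries lie between 54 and 106.7 CPM, with the lowest in clone A2 at day 28 and the highest in the parental line at day 56.

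Against the parental line most genes differed at each day in both labelled genotypes. Of 17377 genes tested, 11834 passed an adjusted p of 0.05 at day 28 in libraries labelled heterozygous (6059 higher, 5775 lower) and 10912 in libraries labelled homozygous (5427 higher, 5485 lower). At day 42 the counts were 12606 (6280 higher, 6326 lower) and 12567 (6424 higher, 6143 lower), and at day 56 they were 12149 (5913 higher, 6236 lower) and 11053 (5416 higher, 5637 lower). Changes of at least 2-fold made up 3825 and 2992 of these at day 28, 3292 and 3113 at day 42, and 4828 and 3601 at day 56. At day 42, upper-quartile scaling moved the median log2 fold change of all genes to 0.11 in the first comparison and 0.10 in the other. It raised the share of called genes that were higher to 57.9% in both, so the near-even balance of directions at that day rests on the scaling.

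At day 28 the libraries of the edited clones (n = 6 for each label) were set against 5 parental libraries to ask how the lines differ early in maturation. MYC, a transcription factor that drives growth, fell from 1070 ± 104 CPM (SD) in the parental line to 16.8 ± 4.17 in libraries labelled heterozygous and 15.7 ± 3.49 in libraries labelled homozygous. These falls were 64.1-fold and 68.2-fold (adjusted p = 2.31e-13 and 3.61e-13), and each of the 12 libraries of the edited clones lay below each of the 5 parental ones. ONECUT3, a transcription factor of the cut homeobox class, rose 47.1-fold and 33.8-fold (5.56 ± 0.21 and 5.08 ± 0.21). The endocytic receptor gene LRP2 rose by 4.93 ± 0.85 and 5.65 ± 0.86, and in the libraries labelled homozygous the secreted signalling genes BMP7 and FST rose by 5.18 ± 0.78 and 4.72 ± 0.66. In the libraries labelled heterozygous the adenylyl cyclase gene ADCY8 (4.86 ± 0.19) and the adrenergic receptor gene ADRA2A (4.84 ± 0.18) were among the 6 largest rises. The calcium-binding protein gene CABP7 fell 26.5-fold and 24.8-fold, the neurotensin receptor gene NTSR1 fell 21.7-fold and 15.4-fold, and G0S2 fell 19.7-fold and 20.5-fold. The libraries labelled homozygous also had less ZNF248 (-5.09 ± 0.95) and HOXB4 (-4.03 ± 0.43).

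Lists of pan-neuronal and synaptic genes were higher at day 28. Of 22 pan-neuronal markers, 18 were higher, 2 lower and 2 not past the threshold in libraries labelled heterozygous (camera adjusted p = 3.84e-06), and 17, 2 and 3 in libraries labelled homozygous (1.68e-05), with 18 higher and 2 lower in each when adjusted over the list alone. The microtubule protein gene MAPT rose by 2.62 ± 0.11 and 2.07 ± 0.11 and TUBB3 by 1.09 ± 0.07 and 0.93 ± 0.07. The synaptic vesicle list had 32 of 39 members higher and 2 lower in the first comparison (4.44e-07) and 27 higher and 2 lower in the other (1.44e-06), the same numbers as when adjusted over the list alone. Its members SYT5 (3.28 ± 0.16 and 2.76 ± 0.15) and SYN1 (1.32 ± 0.07 and 1.06 ± 0.07) rose in both. With an estimated correlation the calls of both lists ended in both comparisons (adjusted p = 0.331 and 0.275 with an estimated correlation, for either list). Among 23 ionotropic glutamate receptor genes and partners, 16 were higher in each comparison and 1 and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.0005 and 0.000525; adjusted p = 0.331 and 0.343 with an estimated correlation). GRIN2A, an NMDA receptor subunit gene, rose by 4.32 ± 0.19 and 4.15 ± 0.19, and GRIA4, an AMPA receptor subunit gene, by 3.25 ± 0.17 and 3.17 ± 0.17. For 16 GABA and glycine receptor genes the counts were 12 higher and 2 lower, then 11 higher and 2 lower (12 and 2 for both when adjusted over the list alone; camera adjusted p = 0.00303 and 0.00154, adjusted p = 0.331 and 0.275 with an estimated correlation). The glycine receptor gene GLRA3 rose 17.8-fold and 20.7-fold. Markers of glutamatergic neuron identity did not pass: 8 of 18 were higher and 6 lower, then 7 and 4 (9 and 8 higher when adjusted over the list alone; camera adjusted p = 0.499 and 0.345, adjusted p = 0.808 and 0.667 with an estimated correlation). Inhibitory (adjusted p = 0.371 and 0.235, 7 of 19 read) and cholinergic and monoaminergic markers (0.688 and 0.61) did not pass either.

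Cholesterol synthesis genes were higher at day 28 for 21 of 24 members and lower for 1 in both comparisons, also when adjusted over the list alone (camera adjusted p = 2.57e-06 and 1.44e-06; adjusted p = 0.331 and 0.275 with an estimated correlation). The lanosterol synthase gene LSS rose by 1.34 ± 0.06 and 1.31 ± 0.06. In the list of the unfolded protein response of the endoplasmic reticulum, 15 of 20 genes were lower and 1 higher in both comparisons, again also when adjusted over the list alone (0.00128 and 0.000792; adjusted p = 0.331 and 0.275 with an estimated correlation). XBP1 fell by 1.37 and 1.29 on the log2 scale (SE 0.05 each). Integrated stress response genes were lower for 14 of 22 in each comparison and higher for 1 and 2, also when adjusted over the list alone (0.00563 and 0.000934; adjusted p = 0.331 and 0.275 with an estimated correlation). Of these CHAC1 (-1.61 ± 0.12 and -2.03 ± 0.12) and DDIT3 (-1.79 ± 0.16 each) fell. The heat shock list passed as lower for the homozygous label (camera adjusted p = 0.0642 and 0.0102; adjusted p = 0.331 and 0.275 with an estimated correlation). Lists of glycolysis (0.433 and 0.103), hypoxia response (0.0642 and 0.0821), oxidative stress (0.659 and 0.428) and p53 targets (0.499 and 0.345) did not pass. HOX genes, which pattern the hindbrain and spinal cord, were lower for 9 of 10 members and for all 10, with none higher, also when adjusted over the list alone (0.00131 and 9.64e-05; adjusted p = 0.331 and 0.275 with an estimated correlation). HOXC4 fell by 2.44 and 2.58 on the log2 scale (SE 0.12 each).

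Some lists of other cell types were higher at day 28. Of 20 neural progenitor and radial glia markers, 15 were higher and 1 lower in libraries labelled heterozygous and 17 and 1 in those labelled homozygous (16 and 17 higher, 1 lower in each, when adjusted over the list alone; camera adjusted p = 0.0113 and 0.000525, adjusted p = 0.58 and 0.455 with an estimated correlation). The transcriptional regulator gene ID4 rose by 4.14 ± 0.31 and 3.95 ± 0.31. Of 23 mesenchymal and fibroblast markers 16 were higher in each comparison and 4 and 3 lower, also when adjusted over the list alone (0.00426 and 0.00788; adjusted p = 0.544 and 0.586 with an estimated correlation). LUM, a proteoglycan gene of connective tissue, rose by 2.49 ± 0.14 and 2.41 ± 0.14. Markers of peripheral and sensory neurons (camera adjusted p = 0.0663 and 0.0358) and of the oligodendrocyte lineage (0.0912 and 0.0285) passed for the homozygous label (adjusted p = 0.331 and 0.275 for either list with an estimated correlation). The former passed in each of the 4 clones alone (0.0151 to 0.0488). Astrocyte (0.764 and 0.714) and neural crest markers (0.764 and 0.501) did not pass. Nor did epithelial (0.637 and 0.892), endothelial (0.966 and 0.714) and choroid plexus markers (0.707 and 0.714). Of these lists only 8 of 21, 6 of 14 and 6 of 15 members were read, so absence of such cells is not shown. Mitochondrially encoded genes took 6.3 ± 0.5% of counts (SD, n = 5) in the parental line, 7.1 ± 1.4% and 8.4 ± 1.1% (n = 6) in the 2 labelled genotypes. Only the latter differed from the parental line (exact permutation p = 0.00216, adjusted p = 0.00324 over 9 comparisons).

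At day 42 (n = 6 per group) GFAP, an intermediate filament gene of astrocytes, stood at 0.786 ± 0.659 CPM (SD) in the parental line, 125 ± 177 in libraries labelled heterozygous and 116 ± 93.5 in those labelled homozygous (log2 fold change 7.30 ± 1.21 and 7.19 ± 1.21; adjusted p = 2.82e-05 and 3.28e-05). Its level differed widely between libraries, from 2.54 to 463 CPM among those labelled heterozygous, and without replicate 1 of clone D5 its log2 fold change was 6.19. The complement regulator gene CFI rose by 6.50 ± 0.97 and 7.41 ± 0.99, and by 5.90 in the first comparison without that same library. The glutamate transporter gene SLC1A3 rose by 5.27 ± 0.87 and 6.06 ± 0.89, and S100B by 4.42 ± 0.55 and 4.82 ± 0.55. In libraries labelled heterozygous the collagen genes COL3A1 and COL11A1 rose by 5.72 ± 1.17 and 5.71 ± 0.79, where COL3A1 stood at 3.22 without replicate 3 of clone D5 and 6.53 without parental replicate 6. GABRB2, a GABA receptor subunit gene, rose by 5.61 ± 0.28 and 4.84 ± 0.28. The protocadherin gene PCDHGB4 fell 39.9-fold and 23.3-fold, MYC fell 14.5-fold and 20.4-fold, and the melanosome gene PMEL fell 13.8-fold and 9.58-fold. Astrocyte markers as a list did not pass (6 of 17 higher and 2 lower, then 8 and 3, the same when adjusted over the list alone; camera adjusted p = 0.578 and 0.437, adjusted p = 0.865 and 0.847 with an estimated correlation). Neural progenitor and radial glia markers did: 15 and 17 of 20 were higher and none lower, also when adjusted over the list alone (0.0161 and 0.00316; adjusted p = 0.776 and 0.801 with an estimated correlation).

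Interferon-stimulated genes, which respond to viral or self nucleic acid, were higher at day 42. All 23 members were higher in libraries labelled heterozygous and 22 in those labelled homozygous, with 1 not past the threshold, also when adjusted over the list alone (camera adjusted p = 9.64e-07 and 3.97e-07; adjusted p = 0.259 and 0.212 with an estimated correlation). IFIT1 rose from 1.29 ± 0.2 CPM (SD, n = 6) to 17.6 ± 3.46 and 17.9 ± 3.93 (3.76 ± 0.17 and 3.78 ± 0.17), and IFI44 rose by 2.19 ± 0.11 and 2.78 ± 0.11. At day 28 the list did not pass, with 3 higher and 8 lower, then 4 and 5, and camera adjusted p = 0.433 and 0.476 (3 and 7, then 4 and 4, when adjusted over the list alone; adjusted p = 0.774 and 0.742 with an estimated correlation). The change in difference from the parental line was tested between days 28 and 56 and not between days 28 and 42: 18 members rose relative to the parental line in each labelled genotype (1.06e-06 heterozygous and 8.06e-07 homozygous; adjusted p = 0.446 and 0.267 with an estimated correlation), with 18 and 19 when adjusted over the list alone. At day 56 the list had 18 of 23 genes higher and 1 lower, then 19 higher and none lower (19 higher in each when adjusted over the list alone; camera adjusted p = 0.000286 and 1.42e-05, adjusted p = 0.481 and 0.49 with an estimated correlation). There MX1 rose by 3.82 ± 0.24 and 2.41 ± 0.23 and IFIT2 by 3.36 ± 0.35 and 4.08 ± 0.35.

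Other nuclear transport genes than XPO7 were lower in the edited clones at days 42 and 56. Of 31 nuclear export and import receptors and Ran pathway genes, 25 were lower and 5 higher in each comparison at day 42, also when adjusted over the list alone (camera adjusted p = 0.000194 and 0.000807; adjusted p = 0.599 and 0.801 with an estimated correlation). At day 56, 22 were lower and 7 higher, then 21 and 6, the same when adjusted over the list alone (0.000955 and 0.00333; adjusted p = 0.481 and 0.52 with an estimated correlation). The importin gene IPO7 fell by 1.32 and 1.35 on the log2 scale at day 42 (SE 0.05 each) and by 1.47 and 1.32 at day 56 (SE 0.12 each), and KPNB1 fell by 1.11 and 1.00 at day 42 (SE 0.06 each). The list did not pass at day 28 (15 of 31 lower in each and 5 and 7 higher, also when adjusted over the list alone; camera adjusted p = 0.0591 and 0.144, adjusted p = 0.544 and 0.656 with an estimated correlation). Cytosolic ribosomal protein genes were lower as well at day 42, with 39 and 43 of 75 lower and 4 and 3 higher (39 and 42 lower when adjusted over the list alone; 0.00463 and 0.000889; adjusted p = 0.776 and 0.801 with an estimated correlation). RPL17 fell by 0.83 and 0.86 on the log2 scale (SE 0.04 each).

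The difference in mitochondrial transcripts between edited clones and parental line was large from day 42 on. Mitochondrially encoded genes took 5.9 ± 0.7% of counts in the parental line at day 42 (SD, n = 6), 30.1 ± 5.4% in libraries labelled heterozygous and 21.2 ± 1.6% in libraries labelled homozygous (exact permutation p = 0.00216 for each pair of groups, adjusted p = 0.00324). At day 56 the shares were 5.1 ± 0.8%, 29.8 ± 7.2% and 20.7 ± 10.1%, where both labelled genotypes differed from the parental line (exact permutation p = 0.00216) and not from each other (exact permutation p = 0.106, adjusted p = 0.136). All 13 protein genes of the mitochondrial genome rose in both comparisons at both days, also when adjusted over the list alone. Their medians were 2.65 and 1.92 at day 42 (camera adjusted p = 1.34e-08 and 3.97e-07; adjusted p = 0.645 and 0.801 with an estimated correlation) and 3.24 and 2.56 at day 56 (3.67e-06 and 6.19e-06; adjusted p = 0.481 and 0.52 with an estimated correlation). MT-ND1 rose by 3.01 ± 0.15 and 2.22 ± 0.15 at day 42, and MT-CYB by 3.64 ± 0.35 and 2.90 ± 0.34 at day 56. Nuclear genes of oxidative phosphorylation moved far less. At day 42, 44 of 76 were higher and 15 lower in libraries labelled heterozygous and 39 and 16 in those labelled homozygous, also when adjusted over the list alone, with medians of 0.17 and 0.16 (0.00599 and 0.0412; adjusted p = 0.774 and 0.801 with an estimated correlation). COX6A1 rose by 0.97 ± 0.05 and 0.66 ± 0.05. At day 56 that list did not pass, with medians of 0.14 and -0.15 (0.174 and 0.143; adjusted p = 0.815 and 0.95 with an estimated correlation), and UQCRC2 fell by 0.70 and 0.67 on the log2 scale (SE 0.08 each).

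**Figure D2:**
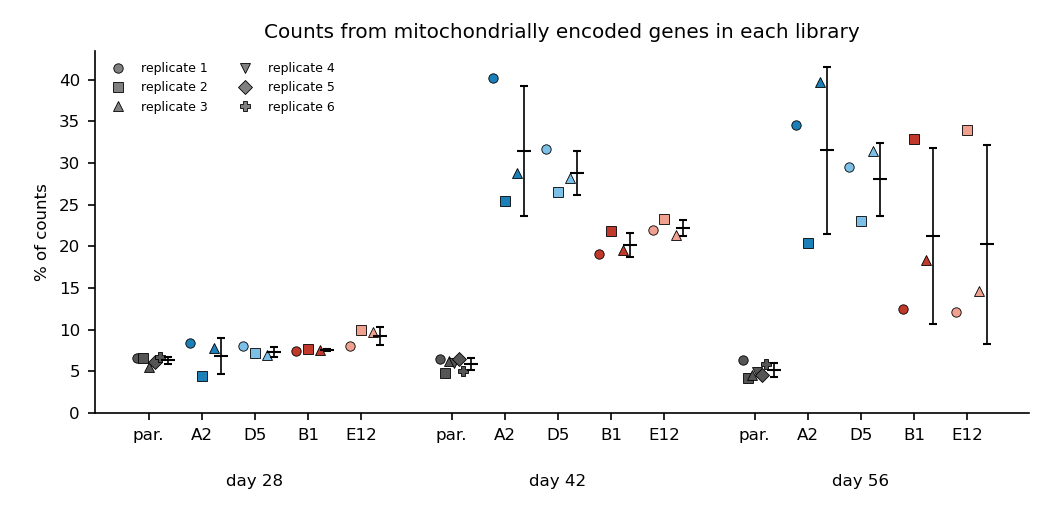
Percent of counts from mitochondrially encoded genes in each of the 53 libraries by line and day; symbols give the replicate number, bars the mean and SD of each line. Parental libraries lie between 4.26% and 6.68%, while at day 56 replicate 2 of B1 and E12 (32.9% and 33.9%) lies apart from their replicates 1 and 3 (12.1% to 18.4%).

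At day 56 (n = 6 per group) lists of astrocyte, progenitor and mesenchymal markers were higher than in the parental line at the preset correlation, and none passed with an estimated correlation. GFAP stood at 2.28 ± 1.6 CPM (SD) in the parental line, 580 ± 558 in libraries labelled heterozygous and 1590 ± 607 in those labelled homozygous (log2 fold change 7.94 ± 0.91 and 9.41 ± 0.97; adjusted p = 2.75e-07 and 1.15e-07). CFI rose by 7.87 ± 0.80 and 9.11 ± 0.83, the hyaluronan receptor gene CD44 by 6.82 ± 0.73 and 8.45 ± 0.77, and the ceruloplasmin gene CP by 6.99 ± 0.87 and 8.52 ± 0.91. Without replicate 2 of clone A2, CP stood at 6.33 in the first comparison. Of 17 astrocyte markers, 12 were higher and 1 lower, then 14 higher and none lower, also when adjusted over the list alone (camera adjusted p = 0.0108 and 0.0002; adjusted p = 0.593 and 0.52 with an estimated correlation). S100B rose by 6.16 ± 0.33 and 5.80 ± 0.33. Progenitor and radial glia markers were higher for 15 and 17 of 20 genes and lower for 1 and none, also when adjusted over the list alone (0.00492 and 5.61e-06; adjusted p = 0.602 and 0.52 with an estimated correlation). FABP7 rose by 6.64 ± 0.81 in libraries labelled heterozygous and VIM by 5.01 ± 0.50 in those labelled homozygous. Of 23 mesenchymal and fibroblast markers, 15 and 20 were higher and 2 and 1 lower, also when adjusted over the list alone (0.0111 and 5.61e-06; adjusted p = 0.593 and 0.49 with an estimated correlation). The matrix gene THBS2 rose by 2.66 ± 0.14 and 2.65 ± 0.14. Among the largest falls were PCDHGB4 (33.6-fold and 21.9-fold), the vascular growth factor gene VEGFD (19.6-fold and 25.3-fold) and DMRTA1 (17-fold and 13.2-fold).

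At day 56 synaptic vesicle and pan-neuronal lists passed in libraries labelled heterozygous and not in those labelled homozygous. The replicate 2 libraries of the clones did not show this difference. Between homozygous and heterozygous libraries their list medians were -0.01 and 0.02, against -0.94 and -0.92 in replicates 1 and 3. Synaptic vesicle genes had 23 of 39 members higher and 4 lower in libraries labelled heterozygous (camera adjusted p = 0.00264; adjusted p = 0.638 with an estimated correlation). The same list had 10 higher and 14 lower in libraries labelled homozygous (median -0.11, mean 0; 0.754; adjusted p = 0.97 with an estimated correlation), the same numbers as when adjusted over the list alone. SYT5, a member of that list, rose in both, by 2.75 ± 0.17 and 1.63 ± 0.17. Pan-neuronal markers had 14 of 22 genes higher and 4 lower in the first comparison (0.0131; adjusted p = 0.638 with an estimated correlation). They had 6 higher and 7 lower in the other (0.895; adjusted p = 0.97 with an estimated correlation), where the median was 0.05 and the mean -0.04. Both counts were the same when adjusted over the list alone. GABA and glycine receptor genes were higher for 13 and 12 of 16 and lower for 1 and 2 (13 and 12 higher, 2 lower in each, when adjusted over the list alone; 0.000128 and 0.00067; adjusted p = 0.481 and 0.52 with an estimated correlation). Cell cycle genes were lower for 22 of 26 members in libraries labelled heterozygous, also when adjusted over the list alone (0.000187; adjusted p = 0.602 with an estimated correlation). In libraries labelled homozygous 9 were lower and 2 higher (3 lower and none higher when adjusted over the list alone; 0.122; adjusted p = 0.95 with an estimated correlation). The kinesin gene CENPE changed by -2.75 ± 0.30 and -1.70 ± 0.29. Lysosome and autophagy genes were higher for 20 and 21 of 28 members and lower for 2 and 4, also when adjusted over the list alone (0.000373 and 0.000175; adjusted p = 0.481 and 0.49 with an estimated correlation). The protease gene CTSD rose by 2.33 ± 0.17 and 1.97 ± 0.17.

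**Figure D3:**
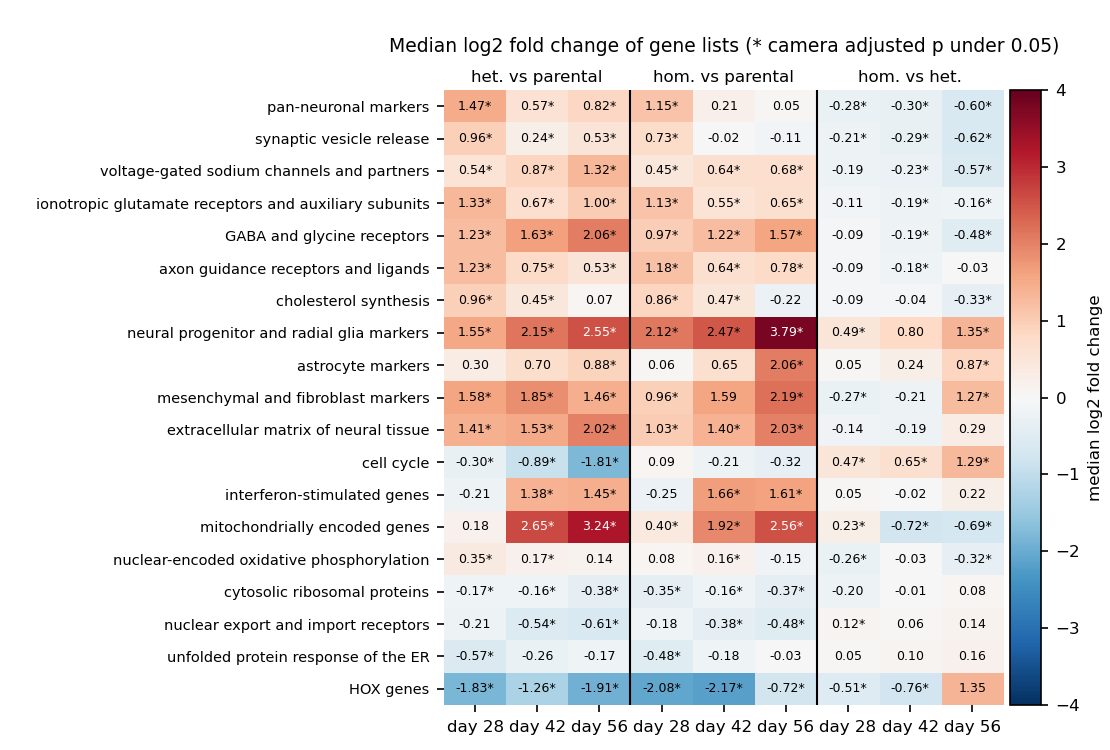
Median log2 fold change of the tested members of 19 gene lists in the 9 comparisons between genotypes; colour and number give the median, and an asterisk marks a camera adjusted p under 0.05 at the preset correlation of 0.01. None of the marked calls holds with an estimated correlation; mitochondrially encoded genes reach 3.24 at day 56 in libraries labelled heterozygous.

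Sodium channel genes, to which the series title points, were mostly higher in the edited clones. At day 28 SCN2A rose from 4.11 ± 0.422 CPM (SD, n = 5) in the parental line to 41 ± 4.8 in libraries labelled heterozygous and 32.9 ± 6.99 in those labelled homozygous (log2 fold change 3.31 ± 0.15 and 3.00 ± 0.15; adjusted p = 3.66e-12 and 1.56e-11). Its rise was 1.56 ± 0.10 and 1.15 ± 0.10 at day 42 and 2.18 ± 0.23 and 1.47 ± 0.23 at day 56. SCN9A rose at each day, by 2.79 ± 0.10 and 2.44 ± 0.10, then 2.56 ± 0.11 and 2.12 ± 0.10, then 3.37 ± 0.27 and 2.38 ± 0.26. The subunit gene SCN2B did likewise, by 1.42 ± 0.16 and 1.04 ± 0.16 at day 28 and 2.06 ± 0.20 and 1.43 ± 0.19 at day 56. SCN1A passed no test at day 28 (-0.82 ± 0.40 and -0.15 ± 0.39; adjusted p = 0.0752 and 0.757) and rose by 1.69 ± 0.27 and 2.86 ± 0.28 at day 56. In libraries labelled heterozygous its value at day 28 passed without clone D5 (-1.69), without D5 replicate 2 (-0.98) or replicate 3 (-1.07), and on replicates 1 and 3 alone (-0.73). SCN8A fell by 0.60 on the log2 scale (SE 0.16, adjusted p = 0.00257) in libraries labelled heterozygous at day 28. It was 0.33 ± 0.12 higher at day 56, a call that ended without parental replicate 1 (0.27), without D5 replicate 1 (0.26), without D5 altogether (0.27) and on replicate 2 of the clones alone (0.18). SCN4B fell by 0.50 on the log2 scale (SE 0.12) at day 28 in libraries labelled homozygous (-0.36 and not past the threshold on replicate 2 of the clones alone) and rose by 1.00 ± 0.12 and 0.80 ± 0.12 at day 56. Of the 18 genes in the list of sodium channels and partners, 13 were higher and 2 lower at day 28 in each comparison (13 higher in each, and 3 and 2 lower, when adjusted over the list alone; camera adjusted p = 0.00664 and 0.00611; adjusted p = 0.331 and 0.313 with an estimated correlation). At day 42 the numbers were 13 higher and 1 lower in each (0.00445 and 0.0184; adjusted p = 0.664 and 0.801 with an estimated correlation). At day 56 they were 15 and 11 higher with none lower (0.000128 and 0.00262; adjusted p = 0.481 and 0.52 with an estimated correlation), and the numbers of both days were the same when adjusted over the list alone.

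**Figure D4:**
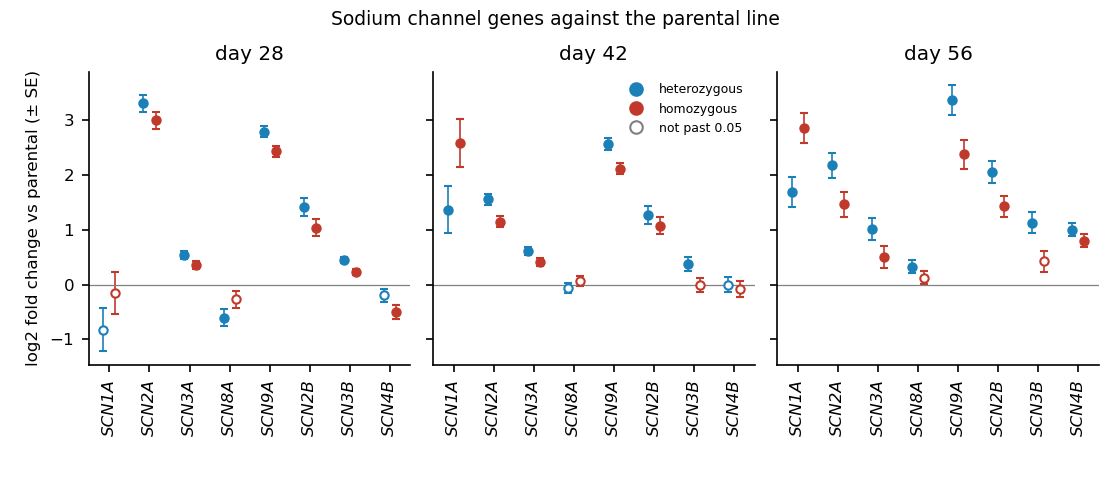
Log2 fold change against the parental line (± SE) of sodium channel genes at each day, for libraries labelled heterozygous (blue) and homozygous (red); open symbols did not pass an adjusted p of 0.05. SCN2A and SCN9A lie above 0 at each day, and SCN1A lies above 0 only from day 42 on.

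Each of the 4 clones was also set alone against the parental line (n = 3 against 5 or 6). At day 28, 9358 genes passed with the same sign in A2 and D5 and 8954 in B1 and E12; the counts were 11352 and 10068 at day 42 and 9739 and 8194 at day 56. At day 42, 631 genes were called with opposite signs in B1 and E12. At all 3 days 3261 genes were higher and 3507 lower in libraries labelled heterozygous, where independent overlap gives 745 and 754, and 2482 were higher and 2764 lower in libraries labelled homozygous, against 625 and 629. Fold changes of the 2 labelled genotypes correlated across genes with r = 0.95, 0.93 and 0.88 at days 28, 42 and 56 (genes are not independent replicates). Both comparisons share the parental libraries, which alone gave r = 0.56, 0.47 and 0.48 in simulated data with no change. The covariance of the fold changes was 0.763, 0.71 and 0.95 against 0.018, 0.014 and 0.02 in the simulation. With separate parental libraries for each genotype, r was 0.94 and 0.93 at day 28, 0.91 and 0.92 at day 42, and 0.88 and 0.84 at day 56. Called genes higher in both numbered 4917, 5325 and 4379, where independent overlap gives 1892, 2322 and 1843, and those lower in both 4885, 5334 and 4738, against 1823, 2236 and 2023. No unedited or mock-edited clone is among the libraries, so genes that all 4 clones share cannot be parted from what any clone of this line would show.

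The direct comparison of libraries labelled homozygous with those labelled heterozygous (n = 6 each) asks what the second edited copy adds. At day 28 the clearest difference lay in cell cycle genes, of which 23 of 26 were higher and none lower in libraries labelled homozygous (25 when adjusted over the list alone; camera adjusted p = 3.39e-21; adjusted p = 0.233 with an estimated correlation). CDK1 was higher by 0.69 ± 0.11 and the topoisomerase gene TOP2A by 0.50 ± 0.07 (0.32 and not past the threshold with each library's trend on GC content and length removed). OLIG1, a transcription factor gene of the oligodendrocyte lineage, was higher by 1.58 ± 0.20, and SLFN11 by 1.70 ± 0.22 (3.26-fold). Synaptic vesicle genes were lower for 10 of 39 members with none higher (14 lower when adjusted over the list alone; 0.000107; adjusted p = 0.749 with an estimated correlation). Pan-neuronal markers were lower for 7 of 22 (9 when adjusted over the list alone; 0.000111; adjusted p = 0.634 with an estimated correlation). MAPT fell by 0.55 on the log2 scale (SE 0.10), a call that ended without clone B1 (-0.41) and on replicate 2 of the clones alone (-0.61). Of the synaptic vesicle, pan-neuronal and sodium channel lists, 1 of 3 passed as lower without D5 and 2 of 3 without B1. TMEM121 (-1.54 ± 0.20) and the protocadherin gene PCDHA9 (-2.11 ± 0.24) were lower in both homozygous clones than in the heterozygous ones. TMEM121 stood at 1.11 CPM in the parental line, 5.21 in libraries labelled heterozygous and 1.76 in those labelled homozygous. For PCDHA9 the levels were 1.49, 4.93 and 1.13 CPM, so for both genes the heterozygous label lay furthest from the parental line. In all 1545 genes passed, 721 higher and 824 lower, of which 42 differed by at least 2-fold. On replicate 2 of the clones alone, with the parental libraries kept, edgeR called 1 gene, which has only an identifier, so none of the calls of genes named here held there. Without replicate 2 of clone A2, whose XPO7 level was the lowest of all libraries, 4139 genes passed, against 773 without B1 replicate 1, 826 without B1 replicate 3 and 878 without E12 replicate 1. A fit of all 3 days called 1602 genes there, of which 28% were higher. In edgeR fits of the edited libraries alone, 543 genes parted the labelled genotypes (3617 at an unadjusted p under 0.05). Clones A2 and B1 differed from D5 and E12 in 478 genes (2746 unadjusted), and A2 and E12 from D5 and B1 in 1, the antisense RNA gene A2M-AS1, named after its value was seen (412 unadjusted).

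At day 42 the comparison called 4630 genes, 2502 higher and 2128 lower in libraries labelled homozygous (n = 6 each). Genes that respond quickly to activity were higher: 12 of 26 immediate early genes rose and 1 fell (15 and 1 when adjusted over the list alone; camera adjusted p = 0.0112; adjusted p = 0.913 with an estimated correlation). EGR2 rose by 1.97 ± 0.40 and FOS by 1.05 ± 0.22. OLIG2 was higher by 2.01 ± 0.30. The rises of FOSB (2.65 ± 0.63) and NR4A1 (2.13 ± 0.47) were not seen without clone B1 (-0.04 and 0.21), and those of FOSB, NR4A1 and FOS missed the threshold without A2 (2.48, 2.00 and 0.71). On replicate 2 of the clones alone FOSB (2.60), NR4A1 (2.04), FOS (0.84) and EGR2 (2.27) all missed it. Synaptic vesicle genes were lower for 15 of 39 (18 when adjusted over the list alone; 1.14e-06; adjusted p = 0.782 with an estimated correlation), and none were higher; SYN2 (-0.74 ± 0.14) and SYT5 (-0.31 ± 0.05) were among them. Of the 18 sodium channel genes and partners, 2 were higher and 9 lower, also when adjusted over the list alone (0.0037; adjusted p = 0.782 with an estimated correlation). FGF13, which codes for a channel partner, fell by 0.66 on the log2 scale (SE 0.13), and SCN9A by 0.43 (SE 0.10), a call that ended without clone E12 (-0.26). GRIN1 fell by 0.85 (SE 0.11) and the GABA receptor gene GABBR2 by 0.54 (SE 0.10). All 13 mitochondrially encoded genes were lower, also when adjusted over the list alone (3.99e-09; adjusted p = 0.732 with an estimated correlation), and MT-ND1 fell by 0.79 (SE 0.14). On replicate 2 of the clones alone MT-ND1 (-0.36), SYN2 (-0.72), FGF13 (-0.62) and SCN9A (-0.54) missed the threshold, and the median of the mitochondrially encoded list was -0.31 there against -0.93 in replicates 1 and 3. Without clone E12 camera called 0 of the synaptic vesicle, sodium channel and pan-neuronal lists (also 0 at an unadjusted p under 0.05; highest adjusted p = 0.758). The 2 homozygous clones differed from each other in 8845 genes at this day, and the count was 9382 without B1, 3005 without E12 and 2039 without A2. On the edited libraries alone edgeR called 2785 genes between the labelled genotypes, against 3636 between A2 with B1 and D5 with E12 and 0 for the third pairing (1392 at an unadjusted p under 0.05). Differences between single clones were thus as wide as those between the labels at this day.

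At day 56 the comparison called 6338 genes, 3390 higher and 2948 lower (n = 6 each). Cell cycle genes were higher in libraries labelled homozygous for 25 of 26 members, also when adjusted over the list alone (camera adjusted p = 3.76e-07; adjusted p = 0.473 with an estimated correlation), and CCNB2 rose by 1.58 ± 0.38 (0.97 and not past the threshold without E12). Progenitor markers were higher for 10 of 20, also when adjusted over the list alone (0.000177; adjusted p = 0.473 with an estimated correlation), among them HES5 (3.03 ± 0.66) and PAX6 (1.58 ± 0.30). Of 39 synaptic vesicle genes 26 were lower and none higher (33 lower when adjusted over the list alone; 3.89e-13; adjusted p = 0.473 with an estimated correlation), among them VAMP1 (-1.19 ± 0.13). Pan-neuronal markers were lower for 17 of 22 (19 when adjusted over the list alone; 3.85e-09; adjusted p = 0.473 with an estimated correlation), and SNAP25 fell by 0.93 (SE 0.16). Of the 18 sodium channel genes and partners 11 were lower and 1 higher (13 and 1 when adjusted over the list alone; 0.000629; adjusted p = 0.473 with an estimated correlation). Here SCN2A fell by 0.71 (SE 0.22), SCN9A by 0.99 (SE 0.25) and SCN3B by 0.70 (SE 0.19), while SCN1A rose by 1.17 ± 0.27. The calls of SCN2A and SCN3B ended without clone D5 (-0.57 and -0.58) or without E12 (-0.45 and -0.53), and that of SCN9A without D5 (-0.89). On the edited libraries alone 4596 genes parted the labels, and edgeR called 0 for each of the other pairings (234 and 1124 at an unadjusted p under 0.05). These differences rest on replicates 1 and 3 of the clones. In fits of the edited libraries alone, the comparison called 16 genes among the 4 libraries numbered 2, against 8264 among the other 8, and of those 8264 genes 49.9% lay in the same direction. A fit of replicate 2 of the clones with the parental libraries kept called 209 genes. In that fit SCN2A stood at 0.24, SCN9A at 0.04, SCN3B at 0.21, SCN1A at -0.04 and HES5 at -1.26, so their directions were turned, and the calls of CCNB2 (0.06), PAX6 (0.24), VAMP1 (-0.69) and SNAP25 (-0.24) ended. On the edited libraries alone, the list medians in the 4 numbered 2 and in the other 8 were -0.31 and 2.29 for cell cycle genes, -0.65 and 2.53 for progenitor markers, and -0.01 and -0.94 for synaptic vesicle genes. The mitochondrial share of counts turned with them, at 20.4% to 23% in libraries labelled heterozygous and 32.9% to 33.9% in those labelled homozygous for number 2. For numbers 1 and 3 it was 29.5% to 39.7% and 12.1% to 18.4%.

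**Figure D5:**
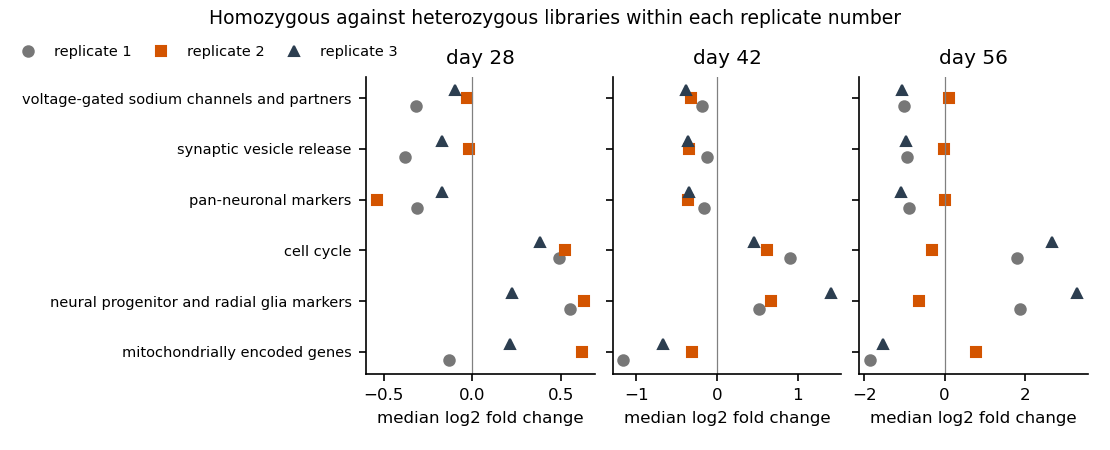
Median log2 fold change of 6 gene lists between libraries labelled homozygous and heterozygous, computed within each replicate number (4 libraries per point, 2 per label) at each day. At day 56 replicate 2 lies on the other side of 0 from replicates 1 and 3 for cell cycle genes (-0.31 against 1.80 and 2.68) and mitochondrially encoded genes (0.78 against -1.86 and -1.54).

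The parental line was followed over time to give the background of maturation. Between day 28 (n = 5) and day 42 (n = 6) TH, which codes for tyrosine hydroxylase, rose by 5.66 ± 0.33 (50.5-fold), and CACNG3 rose 21.9-fold. The neurotrophin gene BDNF rose by 4.13 ± 0.29 and SCN2A by 3.08 ± 0.20, while the Notch target gene HES1 fell by 5.86 on the log2 scale (SE 0.45) and HES5 by 4.26 (SE 0.59). Synaptic vesicle genes were higher for 34 of 39 members and lower for 1, also when adjusted over the list alone (camera adjusted p = 5.61e-11; adjusted p = 0.349 with an estimated correlation). SYN3 rose by 3.99 ± 0.28. Cytosolic ribosomal protein genes were lower for 66 of 75 (68 when adjusted over the list alone; 1.01e-09; adjusted p = 0.67 with an estimated correlation). Between days 42 and 56 cholesterol synthesis genes rose, for 21 of 24 members, also when adjusted over the list alone (2.84e-15; adjusted p = 0.0959 with an estimated correlation). DHCR7 rose by 1.50 ± 0.10 and MVD by 1.77 ± 0.15. LYZ, CTSS and ITGB2, genes typical of myeloid cells, fell (-6.24 ± 0.32, -4.32 ± 0.25 and -3.48 ± 0.20). Of all genes tested, 10127 passed between days 28 and 42 (5038 higher, 5089 lower) and 7754 between days 42 and 56 (3650 higher, 4104 lower). Day and any handling that went with it cannot be parted.

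Whether the difference from the parental line itself changed between days 28 and 56 was tested as an interaction, which called 9185 genes in libraries labelled homozygous (4720 upward, 4465 downward) and 9012 in those labelled heterozygous (4040 upward, 4972 downward). GFAP gained 9.48 ± 1.87 and 6.81 ± 1.69, CD44 7.94 ± 0.73 and 6.25 ± 0.72, and COL4A6, a basement membrane collagen gene, 6.91 ± 0.78 and 6.90 ± 0.79 relative to the parental line. FGF10 changed by -3.66 ± 0.49 and -3.79 ± 0.49, and CSMD3 by -3.89 ± 0.31 and -3.78 ± 0.31. Without replicate 3 of D5 at day 28, the value of GFAP in libraries labelled heterozygous was 7.64. The rise of SCN2A over the parental line shrank (-1.49 ± 0.25 and -1.09 ± 0.25), and that of SCN1A grew (3.05 ± 0.55 and 2.55 ± 0.56). Mitochondrially encoded genes gained for all 13 members in both, also when adjusted over the list alone (camera adjusted p = 4.62e-06 and 1.28e-11; adjusted p = 0.593 and 0.446 with an estimated correlation). Cholesterol synthesis genes lost for 20 and 19 of 24, with 1 gaining in each, also when adjusted over the list alone (5.34e-10 and 1.06e-06; adjusted p = 0.267 and 0.446 with an estimated correlation). Pan-neuronal markers lost for 19 and 16 of 22 and gained for 1 and 2 (20 and 17 lost when adjusted over the list alone; 9.71e-07 and 0.00173; adjusted p = 0.593 and 0.771 with an estimated correlation). Spliceosome genes lost for 21 and 26 of 33, with 2 and none gaining (21 and 27 lost, 2 and 1 gained, when adjusted over the list alone; 0.000856 and 1.24e-06; adjusted p = 0.593 and 0.491 with an estimated correlation).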

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

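The tests of mitochondrial transcripts, of cell composition, of an effect in proportion to the number of edited copies, of clone E12 by day and of replicate numbers were chosen only after the results were seen. For depth, GC content and length, any growth with the number of edited copies, and clone E12 over all days, the bounds were written before. The tests of other splits and of pairings of whole clones were written before as well. The fits that give the values for depth, for GC content and length, and for clone E12 were added after seeing the data. Those tests were thus not planned from the start.

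Differences in effect were tested directly. The difference from the parental line changed between days 28 and 56 for 9185 genes in libraries labelled homozygous and 9012 in libraries labelled heterozygous. In libraries labelled homozygous the largest gains were GFAP (9.48), CP (8.29, and 7.54 without parental day 28 replicate 6), CD44 (7.94), ITGB4 (7.44) and COL4A6 (6.91). The largest losses were LHX9 (-3.98), CSMD3 (-3.89), HPCAL4 (-3.76), VEGFD (-3.71) and FGF10 (-3.66). Among sodium channel genes, SCN1A (3.05), SCN8A (0.44) and SCN4B (1.33) gained and SCN2A lost (-1.49). In libraries labelled heterozygous CP (8.62), APOL1 (8.01), COL4A6 (6.90), GFAP (6.81) and CD44 (6.25) gained most, and LMO3 (-4.28), FGF10 (-3.79), CSMD3 (-3.78), OLIG2 (-3.66) and CRABP1 (-3.61) lost most. CP stood at 7.86 there without parental day 28 replicate 6 and at 7.95 without A2 day 56 replicate 2, and GFAP at 7.64 without D5 day 28 replicate 3. SCN1A (2.55), SCN3A (0.49), SCN8A (0.96), SCN9A (0.60), SCN2B (0.66), SCN3B (0.70) and SCN4B (1.22) gained, and SCN2A lost (-1.09). LDHA gained as well, by 2.26 in libraries labelled heterozygous and 1.78 in those labelled homozygous.

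Some of these smaller calls ended when 1 library was left out or under another setting. With RLE scaling SCN8A in libraries labelled homozygous (0.40) and SCN9A in those labelled heterozygous (0.59) lost theirs, as did SCN8A with DESeq2 (0.40), and SCN9A (0.60) and SCN2B (0.55) in thinned libraries. In libraries labelled homozygous, SCN8A lost its call without any of 7 libraries (0.34 to 0.42, lowest without B1 day 56 replicate 2). In libraries labelled heterozygous, SCN9A lost it without any of 17 libraries (0.52 to 0.61, lowest without parental day 56 replicate 2). SCN3A did so without parental day 28 replicate 5 (0.47), parental day 56 replicate 2 (0.42), or day 56 replicate 1 of A2 or D5 (0.46 each). SCN2B did so without parental day 28 replicate 3 (0.63), A2 day 28 replicate 1 (0.61), or D5 day 28 replicate 2 or day 56 replicate 1 (0.60 each).

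Clones of one label were tested too. D5 and A2 differed in 395, 2228 and 44 genes at days 28, 42 and 56. E12 and B1 differed in 844, 8845 and 13. Variation within lines was wider at day 56 (coefficient 0.209, 0.098 at day 42), so its low counts do not show alike clones.

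Single libraries lay apart from the others of their genotype and day. Replicate 2 of A2 at day 28 had 54 CPM of XPO7 (others 78.1 to 90.1) and 4.41% mitochondrial counts (6.91 to 8.4). Replicate 3 of D5 at day 56 held 20.4 M counts (36.5 to 40.8), and parental replicate 1 at day 56 held 50.3 M (52.8 to 54.1). GFAP reached 2.40 CPM in D5 day 28 replicate 3 (0.209 to 0.848), 463 in D5 day 42 replicate 1 (2.54 to 140) and 2.03 in parental day 42 replicate 2 (0.147 to 0.833). MYC stood at 15.7 CPM in B1 day 56 replicate 1 (20.1 to 21.9 in the others). Of 45 groups tested 8 held such a library, where chance alone gives about 1 in 20.

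Other splits of the same libraries, 100 per result with the real one, exclude chance placement of single libraries for the counts of genes. They break up the clones, so they do not show that whole clones placed by chance would give fewer. For the direct comparison the 3 pairings of whole clones are too few for a share under 0.05. On the edited libraries alone the labels gave 543, 2785 and 4596 genes at days 28, 42 and 56. The highest other pairing gave 478, 3636 and, by edgeR, 0 (1124 at an unadjusted p under 0.05), so at day 42 A2 with B1 against D5 with E12 called more genes than the labels did. Highest counts of the other splits of single libraries are given in parentheses. Real counts for the heterozygous, homozygous and direct comparisons were 11834 (10276), 10912 (9042) and 1545 (53) at day 28. They were 12606 (7341), 12567 (8427) and 4630 (4090) at day 42, and 12149 (6081), 11053 (7581) and 6338 (6105) at day 56. The parental line over time gave 10127 (8652) and 7754 (4597). The interactions gave 9012 (8045) for the heterozygous label and 9185 (9485) for the homozygous label, where 2 of 100 splits, the real one included, gave as many. For all other counts of genes only 1 of 100 did, the real one. Genes past the threshold in both clones numbered 9358 (5390) and 8954 (4976) at day 28 and 9739 (136) and 8194 (3) at day 56. At day 42 they numbered 11352 and 10068, where edgeR called 0 in each other split (up to 3277 and 4470 at an unadjusted p under 0.05). For counts of gene lists chance cannot be excluded. In the order above, the real counts were 24 (33), 29 (32) and 15 (29) at day 28, reached by 23, 9 and 56 of 100 splits. They were 25 (29), 16 (33) and 18 (29) at day 42, reached by 6, 38 and 52, and 30 (34), 24 (34) and 25 (33) at day 56, reached by 7, 26 and 23.

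The 4 edited clones shared much of their difference from the parental line. At day 42, though, B1 and E12 had 631 genes called with opposite signs and 8845 that differed. Depth is argued against, since at least 94.3% of the called genes stayed called with the same sign once libraries were thinned to equal totals. Removal of each library's trend on GC content and length kept at least 79.3%, which argues against that trend as the whole cause, while its part in the other genes cannot be told apart because the preset bound of 80% was missed. An effect in proportion to the number of edited copies, as labelled, would give a slope of the homozygous on the heterozygous fold changes near 2. The slopes were at most 0.92, and taken the other way round and inverted, where noise can only raise them, at most 1.14, which argues against such an effect as the whole cause. A smaller growth with the number of copies cannot be told apart: the bound of 1 written for the first slope was wrong, since noise in the heterozygous values lowers that slope. What stays open, and was not tested, is a difference that any clone of this line would show, since no unedited clone is among the libraries.

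Mitochondrially encoded transcripts took a larger share of counts in the edited clones at days 42 and 56. More mitochondria per cell, with their nuclear-encoded parts made in proportion, is argued against: the medians of the nuclear-encoded list were at most 0.08 of those of the mitochondrially encoded list. Damaged cells that keep nuclear and mitochondrial RNA cannot be told apart from a regulated change. The median of nuclear-retained RNAs lay at most at 0.36, under the bound of 0.5 written for this test, yet only 4 such RNAs were read and they went both ways (from -0.61 to 1.54 in libraries labelled heterozygous at day 42), so that median decides nothing. A response to the edit or to clone derivation stays open as well.

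Neuronal genes were lower and cell cycle and progenitor genes higher in libraries labelled homozygous than in those labelled heterozygous. Without clone E12, 3 neuronal lists were lower and past the camera threshold in 6 of 9 combinations with day. All 6 were at days 28 and 56, where other splits of single libraries passed a median of 15 and 16 of 57 lists. Passes this common do not decide on that clone. At day 42 camera passed 0 of 3 (also 0 at an unadjusted p under 0.05), so E12 alone may account for that day's pattern. The day 28 passes rest partly on D5 (1 of 3 without it, highest adjusted p = 0.591) and B1 (2 of 3, 0.723). All these calls are at the preset correlation. With all clones camera passed 0 of 57 with an estimated one (2, 2 and 1 at an unadjusted p under 0.05 at the 3 days). A larger share of progenitor or glial cells cannot be told apart, since the medians of 4 neuronal lists lay up to 0.46 apart at day 56, between the bounds of 0.3 and 0.5. A difference between replicate numbers at day 56 could account for that day's difference in the neuronal lists, as only 49.9% of the genes called in replicates 1 and 3 went the same way in replicate 2, while an effect of the second edited copy stays open.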

How the results depend on the processing

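Chosen only after seeing the data were the fits with upper-quartile scaling, thinned libraries, the trend on GC content and length removed, no mitochondrially encoded genes, no shallow libraries, parental libraries alone, and replicate numbers apart. So were leaving out clones for single genes and gene lists, and leaving out libraries for gene lists and genes in both clones; both were planned for the other counts of genes. Counts of genes against the parental line stayed within 1.5 times under every alternative run but glmTreat and, at day 42, the line as a random block. Across the alternatives within 1.5 times they ranged from 9678 to 13653 (heterozygous) and 7501 to 13416 (homozygous) at day 28, 10717 to 13829 and 10688 to 13756 at day 42, and 9640 to 12914 and 8243 to 11966 at day 56. Those over time in the parental line, of both interactions and in both clones stayed within 1.5 times under all alternatives run. A fit with no low-count filter, which removed no gene, says nothing of stability. Of 15486 alternatives computed for 507 values of single genes, that fit included, 15111 kept direction and side of the threshold, 298 no longer passed, 56 newly passed and 21 changed sign. Depth and spread limit calls, so a gene not called is not shown to be unchanged. Where a result changed below, the cause was not tested unless the setting itself asks for a larger change or holds fewer libraries.

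Counts of genes moved by more than 1.5 times in these settings. Tested against a fold of 1.5 (glmTreat), the heterozygous and homozygous counts were 5114 and 3950 at day 28, 4664 and 4515 at day 42 and 6083 and 4497 at day 56, and the direct comparison of homozygous with heterozygous gave 12, 27 and 147. With the line as a random block in limma-voom, whose correlation within lines was 0.22 at day 28 and 0.55 at day 42, the counts at day 42 were 8038 and 8012, and the direct comparison gave 229 at day 28 and 235 at day 42. The direct comparison, 1545 genes at day 28, gave 2557 with DESeq2, 2457 with 5 lines as groups, 543 with only the 2 genotypes compared, 3646 with replicates 1 and 3 alone, 1 with replicate 2 alone (a gene with an identifier only), 3513 without A2 and 412 without B1. Leaving out each library gave 773 (B1 replicate 1) to 4139 (A2 replicate 2), with 826 for B1 replicate 3 and 878 for E12 replicate 1. At day 42, from 4630, it gave 7848 with 5 lines as groups, 2354 with all days in one fit, 2785 with only the 2 genotypes, 2543 with replicates 1 and 3 alone, 744 with replicate 2 alone, 2039 without A2, 9382 without B1 and 3005 without E12. At day 56, from 6338, it gave 209 with replicate 2 alone, 3595 without D5 and 4029 without E12. The cause was not tested.

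Replicate numbers did not pair the libraries, which would need every same-number pair to correlate above 0.1: correlations ran from -0.61 to 0.67, with 2, 7 and 5 of 30 pairs above 0.1 at the 3 days. The number still goes with a structure at day 56, where in each of the 4 clones replicate 2 lay further from replicates 1 and 3 than these from each other (chi-square per degree of freedom 78.26 to 333.33 against 21.89 to 126.36). With the number as a replicate block, the direct comparison gave 661 genes at day 28 and 2855 at day 42, and no other count of genes moved by over 1.5 times. Under that replicate block XPO7 in libraries labelled homozygous at day 28 (0.30, adjusted p = 0.0709), SCN2A in the direct comparison at day 56 (-0.75) and the interaction of SCN9A in libraries labelled heterozygous (0.59) were among the genes no longer past the threshold.

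Counts of gene lists fell to 0 of 57 in all 9 comparisons when camera estimated the correlation between genes, with 6, 8, 2, 3, 3, 2, 2, 3 and 1 lists at an unadjusted p under 0.05 (heterozygous, homozygous and direct at days 28, 42 and 56 in turn). The fry test gave 41 (24 by camera) for the heterozygous label at day 28 and 49 (25) at day 42, 48 (16) and 38 (24) for the homozygous label at days 42 and 56, and 6 (15) for the direct comparison at day 28. For the homozygous label at day 42, 7 lists passed in each clone alone, 8 without B1 and 26 without E12, and in the direct comparison at that day 4 without E12 (18 with it). The cause was not tested.

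XPO7 at day 28 in libraries labelled heterozygous (0.03) became a call with replicates 1 and 3 alone (0.13) and without A2 (0.19), and ran from -0.01 to 0.13 with each library left out. The call in libraries labelled homozygous ended with replicate 2 alone (0.28), without B1 (0.30) and without E12 (0.29). In the direct comparison at day 28 (0.26, and 0.16 to 0.30 with each library left out) XPO7 became a call with the trend on GC content and length removed (0.23), with replicates 1 and 3 alone (0.17), without A2 (0.11) and without D5 (0.44). Upper-quartile scaling made a call of XPO7 in the homozygous label at day 42 (0.14), and replicate 2 alone ended the direct calls at day 42 (0.19) and day 56 (0.23). The cause was not tested.

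Genes that changed sign did so in the direct comparison, except SCN3B in libraries labelled homozygous at day 42 without E12 (0.32). At day 28 these were YPEL3-DT (-0.19), LCN9 (-0.24) and GDPD3 (-0.13) without B1, and ZNF248 and FAR2P1 (0.61 each) without A2. At day 42 they were FOSB without B1 (-0.04), PI15 and SCN1A without E12 (-0.21 each), FAR2P1 (1.25) and PCDHA7 (0.39) without A2, and ITGA1 with replicate 2 alone (0.88). At day 56 they were PCDHA7 without A2 (0.13) and, with replicate 2 alone, COL6A3 and HES5 (-1.26 each), NUP37 (-0.01), SCN1A (-0.04), SCN2A (0.24), SCN9A (0.04), SCN2B (0.29) and SCN3B (0.21). The cause was not tested.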

Other observations

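The genes that part every pairing of clones and the levels per line given below were chosen only after their values were seen. Genes by which growing neurons find and join their partners were higher in the edited clones at day 28 (n = 6 for each label against 5). Of 42 axon guidance receptors and ligands, 36 were higher and 3 lower in libraries labelled heterozygous and 33 and 3 in those labelled homozygous, also when adjusted over the list alone (camera adjusted p = 3e-07 and 1.65e-07; adjusted p = 0.331 and 0.275 with an estimated correlation). EPHB2 rose by 1.18 ± 0.05 and 1.02 ± 0.05, while PLXND1 changed by -2.54 ± 0.12 and -2.38 ± 0.12. Of 29 neurexin and presynaptic adhesion genes, 24 and 23 were higher and 3 and 2 lower, also when adjusted over the list alone (8.02e-06 and 1.44e-06; adjusted p = 0.331 and 0.275 with an estimated correlation). NRXN3 rose by 3.24 ± 0.15 and 3.07 ± 0.15, and CNTNAP5 rose 17-fold and 14.3-fold. Of 34 voltage-gated potassium channel genes and partners, 22 and 19 were higher and 5 and 6 lower, also when adjusted over the list alone (0.00535 and 0.0091; adjusted p = 0.331 and 0.352 with an estimated correlation). KCNC2 rose 23.8-fold and 16.4-fold at day 28 and by 3.38 ± 0.21 and 2.43 ± 0.21 at day 56. In the direct comparison at day 56 that list was lower for 17 of 34 genes and higher for 1, also when adjusted over the list alone (8.57e-05; adjusted p = 0.473 with an estimated correlation). There KCNC2 (-0.95 ± 0.20) and KCNAB2 (-1.11 ± 0.14) were lower, and both calls ended on replicate 2 of the clones alone (-0.27 and -0.46). Glycolysis genes gained on the parental line between days 28 and 56 for 14 of 21 genes and lost for 1 in libraries labelled homozygous, and for 13 and 2 in those labelled heterozygous (14 gained in each when adjusted over the list alone; 0.00081 and 0.000154; adjusted p = 0.593 and 0.615 with an estimated correlation). LDHA, which codes for lactate dehydrogenase A, stood at -1.78 ± 0.06 and -1.79 ± 0.06 at day 28 (heterozygous, then homozygous) and gained 2.26 ± 0.16 and 1.78 ± 0.16 by day 56. The list of schizophrenia rare-variant genes did not pass in any of the 9 comparisons between genotypes (camera adjusted p from 0.319 to 0.767).

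A small set of genes parted the labelled genotypes in each of the 4 pairings of a homozygous with a heterozygous clone at each day, 10 higher and 6 lower in libraries labelled homozygous (n = 6 each; 62, 514 and 255 higher and 34, 411 and 433 lower at days 28, 42 and 56 taken alone). The ubiquitin ligase gene ARIH2 was higher by 0.67 ± 0.06, 0.84 ± 0.04 and 0.88 ± 0.09, and PAN2, which codes for a deadenylase subunit, by 1.06 ± 0.12, 1.24 ± 0.07 and 1.13 ± 0.09. The heat shock gene HSPA1A changed by -1.32 ± 0.13, -1.18 ± 0.07 and -1.69 ± 0.18 at the 3 days. Its levels were 6.65, 7.7 and 12 CPM in the parental line, 25.3, 25.6 and 33.8 in libraries labelled heterozygous and 10, 11.2 and 10.5 in those labelled homozygous. At day 28 the calls of ARIH2, PAN2 and HSPA1A ended on replicate 2 of the clones alone (0.72, 1.16 and -1.69).

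Levels per line show genes that follow single clones. ZNF248 stood at 12.8, 13.4 and 14.2 CPM in the parental line and 12.8, 14.9 and 12.4 in clone A2 at days 28, 42 and 56, and at most at 1.28 CPM in any library of D5, B1 or E12. FAR2P1 stood at 27, 34.9 and 26.8 CPM in A2, against 13.3, 5.17 and 3.89 in the parental line. PCDHA9 stood at 11.4 CPM in A2 and 4.62 in D5 at day 56, and at 0.743 in B1 and 0.791 in E12. These levels hold for replicate 2 at day 56 as for the other replicates, which speaks against an exchange of libraries between clones of different labels there. The myeloid gene LYZ fell between days 42 and 56 in all 5 lines, from at least 8.53 CPM in each library at day 42 to at most 0.916 at day 56. No 2 libraries of a line and day were copies of each other: the lowest chi-square per degree of freedom over 76 pairs was 3.99.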
